A study of Solanum lycopersicum with 12 samples.

How the data were processed

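Transcripts of tomato (Solanum lycopersicum) roots and leaves, with or without cadmium (Cd), were measured on 12 single-channel Affymetrix tomato arrays, with 1 sample per array. Per the labels, total RNA was extracted with RNeasy columns, and 100 ng of it was turned into biotin-labelled cRNA. The titles give 4 groups of 3 arrays: root control, root Cd, leaf control and leaf Cd. The source label of the 3 leaf arrays titled as Cd-treated says that those leaves were without Cd. These arrays were grouped by their title, since only the title separates the 6 leaf arrays, and the contradiction applies to every leaf result. The labels give no dose, treatment time, plant age or cultivar. They do not say whether the 3 arrays of a group come from separate plants, so the p-values measure only the spread between these samples, which may be technical.

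The deposited values are log2 expression per probe set, between 1.55 and 13.29. The submitters' processing notes name MAS5 and RMA, without a version or the role of each. Array medians lay between 7.46 and 7.50 in the root arrays and between 6.85 and 6.89 in the leaf arrays. No label explains this difference, so folds between root and leaf are given less the median difference. Where taking it off enlarges a bound, the bound is given as deposited too. The count of probe sets is given both with the median difference and after median centring. The values were used as deposited. The array holds 10209 probe sets. The 171 control probe sets were left out of the tests, which left 10038. Background was taken per array as the highest of 23 negative control probe sets, which lay between 3.13 and 3.57 in root arrays and between 2.69 and 3.01 in leaf arrays. A gene at or below this level on all 3 arrays of a group is given as at background and its fold as a bound computed from that level (0 on the log2 scale where there is none), a rule chosen after the values were seen. The number of arrays limits the precision.

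Names come from the array's 2007 annotation, which gives a gene symbol to 909 of the 10038 probe sets. The other 9129 are unnamed here, so the named genes describe 9.06% of what was tested. For 885 of the 909 named probe sets the gene record was matched to a current gene table, from which synonyms were taken. Where a gene had several probe sets (82 genes), the probe set with the highest mean over the 12 arrays stood for it, which gave 801 genes. PRO1, a symbol shared by 2 gene records, was left out. Neither table holds descriptions or genome positions, so 176 genes with a locus-number symbol are given with a synonym where there is one.

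Group means were fitted with limma 3.58.1 in R 4.3.3 over all 12 arrays, with the empirical Bayes variance prior (prior degrees of freedom 2.84, residual 8). There were 4 contrasts: Cd minus control in root, Cd minus control in leaf, the difference between these responses, and root control minus leaf control. P-values are two-sided and were adjusted over the 10038 probe sets by the Benjamini-Hochberg method, with a threshold of 0.05. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. Contrasts, thresholds, the 26 gene lists and the rule for naming genes were set before the data were examined. The rule names, for each Cd contrast, the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold whose 3 Cd values all lay on one side of the 3 control values, and up to 4 members of each list, past the threshold or not. It names the 10 genes with the largest difference between the tissues' responses, and the 5 largest in each direction between root and leaf. Other genes named were chosen after their values were seen.

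The lists were tested with limma's camera with the inter-gene correlation preset at 0.01, and again with an estimated correlation and with fry. The fixed lists were defined by symbols and phrases, and phrases could be searched only in symbols and synonyms. With this matching 6 of the 26 fixed lists had no member, 11 had fewer than 5 genes and were not tested, and 9 were tested. The lists without a member were metal transport and sequestration, glutathione S-transferases, endoplasmic reticulum folding, cell wall modification, cytosolic ribosomal proteins, and proteasome and ubiquitin. A further 26 lists were completed by symbol after the annotation was read and before any Cd difference was computed, and 24 of these were tested. They hold genes such as expansins and ribosomal proteins, which the matching of the fixed lists had missed. Overlap between the root and leaf responses was tested with Fisher's exact test (two-sided).

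Equal array numbers in the titles were checked as pairs by correlating, across probe sets, each array's deviations from its group mean. Between control and Cd arrays of the same number the correlation was 0.00, -0.26 and 0.06 in root, so the numbers do not pair the root arrays. It was 0.35, 0.42 and 0.12 in leaf, all above 0.1. Paired values (the replicate block) therefore stand beside the named leaf genes and lists whose call they change. The block pairs the root arrays by number too and takes 1 residual spread over both tissues. Each paired p-value, in leaf and for the difference, thus rests in part on a root pairing that these correlations do not show. Between control root and leaf arrays it was -0.00, -0.10 and -0.11. Between control and Cd arrays of unequal number the correlation reached 0.41 in root (root control 2 with root Cd 1). In leaf it reached 0.07 (leaf control 2 with leaf Cd 3). A value above 0.1 alone therefore does not show pairing.

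The contrasts were refitted with a trended robust prior, median-centred arrays, quantile normalization over the 12 arrays or within a tissue, only the 6 arrays of the tissue, only probe sets above the median brightness, no probe sets shared between genes, array weights, a 2-fold minimum, a replicate block, and with each array left out in turn. The procedure was tested on simulated data, in 10 runs with 200 of the 10038 probe sets changed in root. It called 10.6% of changes of 0.5 on the log2 scale, 59.4% of changes of 1 and 89.0% of changes of 2. Of the simulated root calls 5.20% were false, 3 leaf calls were made in all, and a list of 9 genes shifted by 1 was called in 10 of 10 runs under the preset and the estimated correlation. The other lists were called 0 times in root, and in leaf, where no list was shifted, lists were called 2 times. The simulated values were normal, with 1 SD per probe set that was the same in all 4 groups, as the main fit assumes. They were drawn independently for each probe set. These runs therefore do not show how the list tests behave where the genes of a list correlate. Nor do they show the share of false calls where groups differ in spread, as the wider leaf Cd group does here.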

Results

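The series measured transcript levels in tomato roots and leaves with and without Cd, in 4 groups of 3 arrays. Values below are mean log2 expression ± SD over the 3 arrays of a group, and differences are Cd minus control. Within a group the arrays correlated at 0.960 to 0.994, between control and Cd arrays of a tissue at 0.950 to 0.981, and between tissues at 0.824 to 0.891. The arrays titled as leaf Cd correlated with each other at 0.960 to 0.976, and with leaf controls at 0.950 to 0.971. Among leaf arrays, leaf Cd 3 stood apart. Its array weight was 0.155, against 0.668 to 1.60 in the other leaf arrays and 8.12 for root control 1. Its mean correlation was 0.963 with its own group and 0.964 with the leaf controls, the only leaf array no closer to its own group.

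The first comparison asked which transcripts differed between roots with and without Cd. P4 and PR1b1, defence proteins of the PR-1 family, had the largest rises. P4 rose from 3.44 ± 0.13, above background on 2 of 3 control arrays, to 9.46 ± 2.31 (64.9-fold, adjusted p = 0.0132). PR1b1 rose from 5.59 ± 0.44 to 10.56 ± 1.73 (31.4-fold, adjusted p = 0.00481). These sizes moved with single arrays: the log2 difference of P4 (6.02) was 7.31 without root Cd 1, 5.08 without root Cd 2 and 4.14 with array weights. That of PR1b1 (4.97) was 5.89, 4.18 and 3.25. LOC544276, listed under the synonym ICL, rose from 5.18 ± 0.95 to 9.78 ± 0.37 (24.3-fold, adjusted p = 0.000618). The largest fall was that of HSP21, a small heat shock protein of plastids, from 7.96 ± 1.5 to 4.56 ± 0.48 (10.5-fold lower, adjusted p = 0.0149). Its log2 difference of -3.39 was -4.25 without root control 2 and -4.18 with array weights.

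Next among the rises in root came LOC543602 (synonym Eli3), from 5.56 ± 0.78 to 8.55 ± 0.42 (7.91-fold). TSI-1 rose from 4.14 ± 0.76 to 6.76 ± 0.38 (6.15-fold; log2 difference 2.62, and 1.79 with array weights), and ext1, an extensin-like cell wall protein, rose from 5.17 ± 0.81 to 7.78 ± 0.95 (6.11-fold). The sulfate transporter ST2 rose from 3.38 ± 0.43, above background on 2 of 3 control arrays, to 5.59 ± 0.56 (4.62-fold). LOC543717 (synonym TSB) rose 3.07-fold. The metal transporter NRAMP1 rose 3.03-fold, from 7.97 ± 0.53 to 9.57 ± 0.40 (log2 difference 1.60, and 2.25 with array weights), and MTSHP, a mitochondrial small heat shock protein, rose 2.82-fold. After HSP21, the largest falls were those of LOC778303 (4.39-fold lower), CO1, a transcription factor of the CONSTANS family (4.26-fold lower, above background on 1 of 3 Cd arrays), and CAB4, a light-harvesting chlorophyll-binding protein (4.02-fold lower, from 10.85 ± 1.0 to 8.84 ± 0.71). The lipoxygenase LOX1.1 fell from 9.40 ± 0.51 to 7.52 ± 0.22 (3.68-fold lower). CIP1 fell from 10.62 ± 0.04 to 8.86 ± 0.14 (3.39-fold lower, adjusted p = 7.73e-05), and the gibberellin 3-oxidase 3OH-2 from 7.25 ± 0.25 to 5.58 ± 0.34 (3.17-fold lower). ACO6, an ACC oxidase of ethylene synthesis, was 3.0-fold lower, chMDH 2.80-fold lower, and LCY1, a lycopene cyclase of carotenoid synthesis, 2.78-fold lower.

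**Figure D1:**
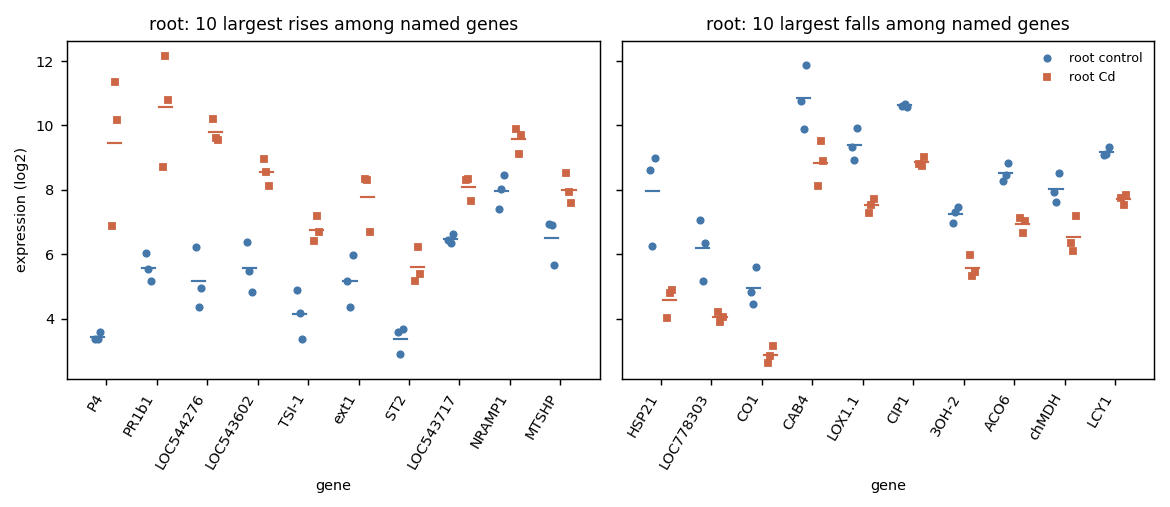
Log2 expression (y axis) of the 10 named genes with the largest rise and the 10 with the largest fall in root (x axis), with 1 point per array, circles for root control, squares for root Cd and a line at each group's mean. In each gene shown the 3 Cd values lie on one side of the 3 control values, and P4 has the widest Cd group (SD 2.31).

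Over all probe sets, 304 passed the adjusted threshold in root, 107 higher and 197 lower with Cd, and 222 of them differed by at least 2-fold. The balance of rises and falls depended on the setting. It was 108 higher and 94 lower with the 6 root arrays fitted alone, 105 and 102 after quantile normalization within root, and 1873 and 1872 with array weights. At an unadjusted p under 0.05, 1744 passed. The groups did not overlap in 27.4% of probe sets, where chance gives 10%. Among the 801 named genes 37 passed, 18 higher and 19 lower. The others included the ABA synthesis enzyme NCED1 (-1.32), the phosphoenolpyruvate carboxylase kinase PPCK2 (at background with Cd, at least 2.28-fold lower), the light-signalling transcription factor HY5 (-1.05), the beta-amylase BMY3 (-0.81). They also included the pectin methylesterase PMEU1 (0.92), the beta-galactosidase TBG1 (1.04), the acid phosphatase APS1 (0.74), the mitochondrial uncoupling protein UCP (0.69) and Dif54 (1.76). Leaving out 1 array took the root count to 118 (root control 1), 123 (root control 3), 85 (root Cd 1) or 136 (root Cd 2). Array weights, which rest mostly on root control 1 and root Cd 1, took it to 3745. Settings were compared for the 23 of these 37 genes that the rule for naming genes covers. Of the 23, ACO6, CIP1, CO1, LCY1, LOC543602, LOC543717, LOC544276, NCED1 and PR1b1 (9) kept their call under all settings in which their probe set was tested. The 14 others of the 23 lost it under at least 1, among them P4 without root control 1 (adjusted p = 0.0506), ST2 without root Cd 2 (0.0519), and CAB4 and MTSHP (up to 0.169).

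Among the fixed lists, that of pathogenesis-related proteins had the lowest camera p-value in root with the preset correlation. Of its 9 measured genes 2 rose (P4 and PR1b1), 7 did not pass over all probe sets, and 8 rose when adjusted over the list alone. The chitinases CHI3 (7.31 ± 0.46 and 9.96 ± 0.96 without and with Cd, adjusted p = 0.113) and CHI14 (5.03 ± 0.87 and 7.44 ± 0.82, adjusted p = 0.0682) did not pass. The list's median difference was 1.06 (camera adjusted p = 3.71e-07; adjusted p = 0.144 with an estimated correlation). In the list completed by symbol, TSI-1 joined P4 and PR1b1 among 14 genes, 3 of which rose (camera adjusted p = 1.13e-07; adjusted p = 0.21 with an estimated correlation).

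Iron acquisition genes were the other fixed list called in root. NRAMP1 and FER, the iron-uptake regulator (10.19 ± 0.16 to 10.98 ± 0.10, adjusted p = 0.0300), rose, and 3 of 5 genes did not pass; 3 rose when adjusted over the list alone. NRAMP3 differed by 0.50 (adjusted p = 0.0806) and the ferric reductase FRO1 by -0.39 (adjusted p = 0.884). The list's median was 0.50 (camera adjusted p = 0.0193; adjusted p = 0.144 with an estimated correlation), and without root control 1 its adjusted p was 0.117.

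Both sulfate transporters of the fixed list of sulfate uptake and assimilation rose in root, ST2 as above and ST1 from 10.89 ± 0.27 to 11.82 ± 0.26 (1.91-fold, adjusted p = 0.0159); the 2 genes were too few for a list test. With the sulfur amino acid and glutathione enzymes added by symbol, 2 of 8 genes rose and 4 rose when adjusted over the list alone (camera adjusted p = 0.00512; adjusted p = 0.209 with an estimated correlation). The metal chelation list had 0 of 7 genes past the threshold over all probe sets and 1 when adjusted over the list alone. Its glutathione synthesis enzymes GSH2 (0.59, adjusted p = 0.102) and GSH1 (0.55, adjusted p = 0.175) and metallothioneins MT3 (0.29) and MT4 (0.29) did not pass (list adjusted p = 0.0648; adjusted p = 0.179 with an estimated correlation).

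CAB4, CAB5 and CAB6A formed the fixed list of photosystem genes, which also serves as the marker list of green tissue in root samples. CAB4 fell. CAB5 (8.57 ± 1.82 and 5.50 ± 0.68, adjusted p = 0.0530) and CAB6A (11.40 ± 0.70 and 10.23 ± 0.54, adjusted p = 0.0843) did not pass; 3 of 3 fell when adjusted over the list alone. In the completed list, with PSBO, PSBP, PSBR, PsbQ, PETE and LOC543978 of the photosystems and electron transport, 1 of 9 genes fell and 9 fell when adjusted over the list alone. The median was -0.95 (camera adjusted p = 3.59e-07; adjusted p = 0.244 with an estimated correlation). Carotenoid synthesis genes fell with them: LCY1, the phytoene synthase PSY2 (7.93 ± 0.11 to 6.94 ± 0.22) and the carotene hydroxylase CrtR-b1 (8.61 ± 0.25 to 7.43 ± 0.28) fell among 11 genes. When adjusted over the list alone 7 fell, and the median was -0.99 (camera adjusted p = 2.57e-06, adjusted p = 0.21 with an estimated correlation). For the phytoene synthase Psy1 the probe sets differed in sign in root. The one with the highest mean differed by -1.05 (adjusted p = 0.0757), and the others by 1.27 (adjusted p = 0.0772) and -1.27 (adjusted p = 0.0127).

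Of the completed lists, 2 more were called in root although 0 of their genes passed over all probe sets. Ethylene receptors and signalling (15 genes, median 0.12) had a camera adjusted p = 0.0334 and an adjusted p = 0.434 with an estimated correlation, and lost its call without root control 1, root control 2 or root Cd 3 (adjusted p up to 0.131). Sucrose and hexose metabolism and transport (13 genes, median 0.21) had a camera adjusted p = 0.0334 and an adjusted p = 0.373 with an estimated correlation, and lost its call without root control 1, root control 3 or root Cd 1 (adjusted p up to 0.0702).

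The other fixed lists tested in root were not called, with camera adjusted p between 0.459 and 0.89. Among heat shock proteins HSP21 fell, while HSP17.4 (2.01, adjusted p = 0.0882), HSP17-6 (-0.41) and HSC80 (-0.08) did not pass. Of 7 jasmonate genes LOX1.1 fell, loxD (0.50) and OPR3 (0.43) did not pass, and loxC was at background; the list's median was 0.15 and its mean -0.11 (0 and -0.13 with genes at background at their bound). None of the 25 genes of the fixed ethylene list passed, ETR4 (0.87), ERF3 (-0.78), ACS6 (-0.69) and ACS2 (0.58) being farthest from 0. The ACC oxidase ACO6, which fell in root, is not a member of that list. Among 5 antioxidant enzymes SODCC.1 (-0.53), CAT2 (-0.32), cat1 (0.31) and APX1 (0.14) did not pass. Neither did CycA2 (0.84), CycB2 (0.50), CDKB1 (0.49) and CYCD3 (0.40) among 9 genes of histones and cell cycle, nor WRKYIId-4 (0.76), LOC543855 (0.41), WRKYIId (-0.19) and WRKY2 (-0.17) among 6 WRKY factors, whose median was -0.08 and mean 0.11.

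In the fixed lists too small to test, ext1, the lone root-hair marker, rose in root, and NCED1 fell while TAS14 (1.66, SD 3.03 with Cd) and ER5 (-0.96) of the ABA and dehydration list did not pass. The peroxidase CEVI-1 (at background in controls and on 2 of 3 Cd arrays, at least 2.09-fold higher on average, adjusted p = 0.268) did not pass. Neither did the transporters AMT1-2 (-0.67), PT2 (0.65) and PT1 (0.59), the flavonoid enzyme CHS2 (-0.41) and the proteinase inhibitor LOC543954 (at background with Cd, at least 1.16-fold lower). CHS1, DFR, the proteinase inhibitor ARPI and the trichome markers SSTLE1 and MTS1 were at background in roots. The lists of aquaporins and phloem markers held only genes matched by name, pip1, a protease (from background, at least 5.47-fold higher, adjusted p = 0.242), and PP2AC1 (0.22) and PP2Ac2 (0.05), phosphatase subunits.

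**Figure D2:**
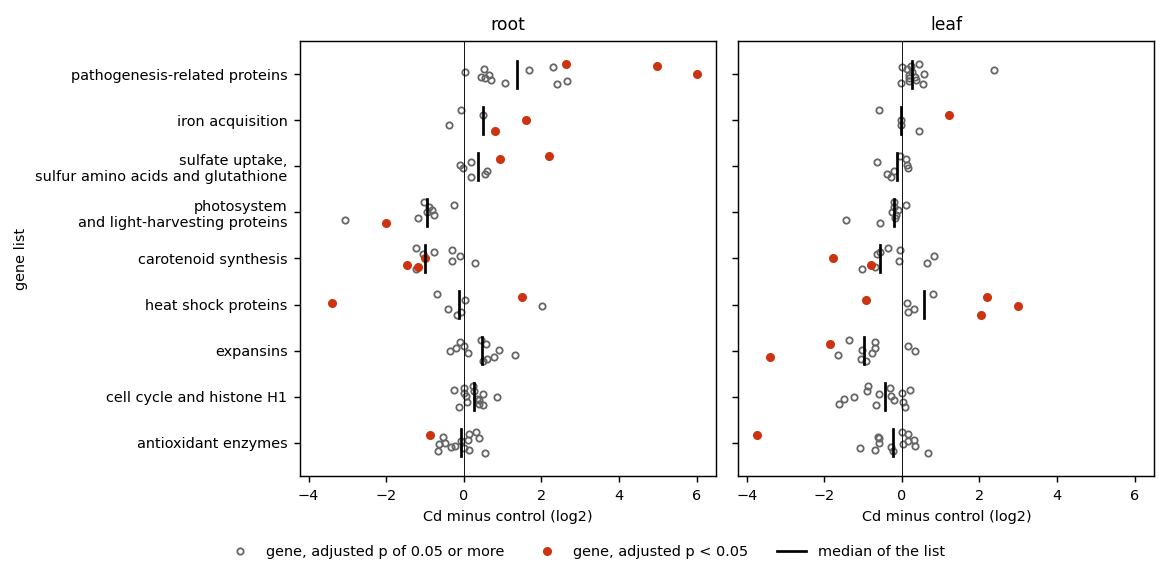
Cd minus control on the log2 scale (x axis) for each gene of 9 lists completed by symbol (y axis) in root and leaf, with filled points for genes past the adjusted threshold, open points for the others and a bar at each list's median. In root the pathogenesis-related median is 1.37 (1.05 with genes at background at their bound), and the photosystem and carotenoid medians are -0.95 and -0.99; in leaf the expansin median is -0.98.

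The second comparison asked the same of leaves, with the 3 leaf arrays titled as Cd-treated against the leaf controls, although the source label of those 3 says without Cd. ACO5, an ACC oxidase of ethylene synthesis, rose from background (2.61 ± 0.06) to 8.49 ± 0.64, at least 50.2-fold higher (adjusted p = 2.99e-05). LOC544282 rose from 3.77 ± 0.23 to 7.75 ± 0.40 (15.8-fold, adjusted p = 0.00460). SODCP.2, the chloroplast copper/zinc superoxide dismutase, fell from 11.18 ± 0.18 to 7.45 ± 0.20 (13-fold lower, adjusted p = 1.48e-05), and the expansin EXP2, a cell wall loosening protein, fell from 9.59 ± 0.35 to 6.19 ± 1.01 (10.6-fold lower, adjusted p = 0.00198).

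Heat shock proteins stood among the rises in leaf: HSP17.4 rose from 3.45 ± 0.32 to 6.44 ± 0.56 (7.92-fold), MTSHP from 5.03 ± 0.18 to 7.21 ± 0.24 (4.55-fold) and ER-SHSP, of the endoplasmic reticulum, from 3.45 ± 0.23 to 5.48 ± 0.18 (4.11-fold). LOC543598 rose from 2.94 ± 0.03, above background on 2 of 3 control arrays, to 6.33 ± 1.25 (10.5-fold; adjusted p = 0.0333, and 0.0839 with arrays paired by number). Its log2 difference of 3.39 was 2.71 without leaf Cd 2 (adjusted p = 0.0761). The alcohol dehydrogenase ADH2 rose from 4.59 ± 1.06 to 7.08 ± 0.44 (5.61-fold; log2 difference 2.49, and 1.89 without leaf control 1), and LOC544070 from 7.58 ± 0.42 to 9.93 ± 0.28 (5.11-fold). The gibberellin 20-oxidase 20ox-2 rose from 2.73 ± 0.41, above background on 1 of 3 control arrays, to 4.63 ± 0.53 (3.74-fold), and the ethylene response factor ERF2 from 8.05 ± 0.18 to 9.63 ± 0.51 (2.99-fold). Among the falls, the subtilisin-like protease SBT2 went from 6.82 ± 0.27 to 4.45 ± 0.53 (5.17-fold lower). CO1 went from 5.59 ± 0.28 to 3.62 ± 0.46 (3.92-fold lower) and the expansin exp11 from 9.34 ± 0.23 to 7.49 ± 0.50 (3.60-fold lower). PSY2 was 3.40-fold lower, 3OH-2 3.35-fold lower, the beta-galactosidase TBG6 3.07-fold lower, HY5 3.01-fold lower and LAT61 2.98-fold lower.

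**Figure D3:**
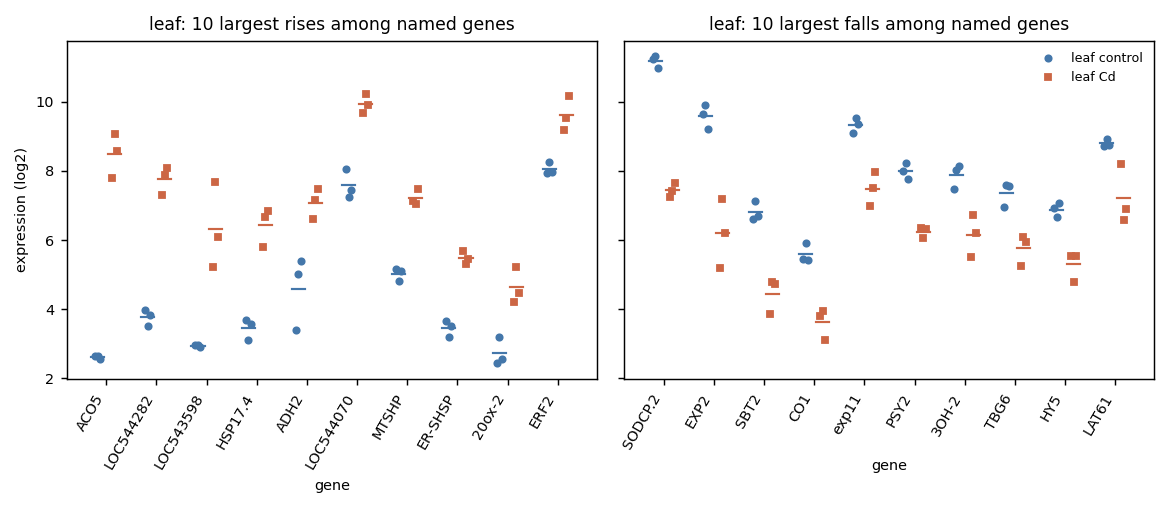
Log2 expression (y axis) of the 10 named genes with the largest rise and the 10 with the largest fall in leaf (x axis), with 1 point per array, circles for leaf control, squares for the leaf arrays titled as Cd-treated and a line at each group's mean. ACO5 goes from a mean of 2.61 to 8.49, and SODCP.2 from 11.18 to 7.45.

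Over all probe sets, 379 passed the adjusted threshold in leaf, 224 higher and 155 lower. Of these, 207 differed by at least 2-fold, 93 higher and 114 lower. At an unadjusted p under 0.05, 1931 passed. The groups did not overlap in 21.7% of probe sets, where chance gives 10%. Among named genes 41 passed, 22 higher and 19 lower. The others included the metal transporter NRAMP3 (1.22, adjusted p = 0.00114), the glutathione S-transferase ctu1 (1.09), the potassium channel LKT1 (1.08) and PMEU1 (0.99). Also higher were the phospholipase PLDa2 (0.85), the diacylglycerol kinase DGK1 (0.84), the transcription factor DREB3 (0.84) and the copper chaperone CCH (0.72). Lower were the auxin-response repressor IAA17 (-1.34), the subtilisin-like protease sbt3 (-1.28), CIP1 (-1.15), CCS, the copper chaperone of superoxide dismutase (-0.84, adjusted p = 0.0153), LCY1 (-0.78) and PTI4 (-0.70). With arrays paired by number (the replicate block) 376 probe sets passed, 258 of them shared with the unpaired count. The balance was then the reverse, with 165 higher and 211 lower. Of the 41 named genes 32 passed paired and 9 did not, among them LKT1 (adjusted p = 0.0673), PLDa2 (0.0804) and DGK1 (0.0982). Another 21 passed only when paired. In root, where the numbers do not pair the arrays, the same block gained 24 named genes and lost 7. A call gained under the block is therefore no sign that the arrays are paired. The count was 127 without leaf control 2, 179 without leaf control 3, 589 without leaf Cd 3 and 65 when the 6 leaf arrays were fitted alone. Of the 41, the rule for naming genes covers 23. Of these 23, ACO5, EXP2, LOC544070, LOC544282, MTSHP, NRAMP3, PSY2, SBT2 and SODCP.2 (9) kept their call under all settings in which their probe set was tested. The 14 others lost it under at least 1 (adjusted p up to 0.232, for ETR5). With the 6 leaf arrays fitted alone ADH2, ERF2, HY5, 20ox-2, 3OH-2, TBG6, LAT61, exp11, Hsp90-1, LOC543598 and ETR5 lost it.

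Antioxidant enzymes were the fixed list called in leaf, with 0 of 5 genes past the threshold over all probe sets and 2 that fell when adjusted over the list alone. Of the 10 splits of the 6 leaf arrays, 8 called at least 1 fixed list, the real split included. A single list call is thus no more than regrouped leaf arrays gave. APX2, an ascorbate peroxidase, went from 10.55 ± 0.25 to 9.46 ± 0.82 (adjusted p = 0.0923, and 0.0443 with arrays paired). SODCC.1 went from 11.81 ± 0.08 to 11.19 ± 0.30 (adjusted p = 0.0561), and APX1 (-0.70) and the catalase CAT2 (-0.27) did not pass. The list's median was -0.63 (camera adjusted p = 0.0323; adjusted p = 0.662 with an estimated correlation), and its adjusted p was 0.0536, 0.0610 and 0.0954 without leaf control 1, leaf control 3 and leaf Cd 2. SODCP.2 and CCS are not members of the fixed list; in the completed list of 15 genes SODCP.2 fell and the test was not passed (camera adjusted p = 0.0928; adjusted p = 0.624 with an estimated correlation).

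Histones and cell cycle genes had a median of -0.59 in leaf (-0.29 with CycB2, at background with Cd, at its bound) with 0 of 9 past the threshold (list adjusted p = 0.0759; adjusted p = 0.662 with an estimated correlation). With arrays paired by number the list passed (adjusted p = 0.000257; adjusted p = 0.202 with an estimated correlation), as did CycA1 (-1.50, adjusted p = 0.00991), CDKB2 (-1.62, adjusted p = 0.0115) and CycA2 (-1.22, adjusted p = 0.0445), which drive cell division. Unpaired, their adjusted p-values were 0.187, 0.270 and 0.236, and CDKB1 (-0.67) did not pass either way. The block gained calls in root too, where the numbers do not pair, so these paired calls rest on a pairing that is not established. The completed list of cell cycle and histone H1 had a median of -0.44 over 14 genes, or -0.30 with CycB2 at its bound (camera adjusted p = 0.0415; adjusted p = 0.624 with an estimated correlation), and its adjusted p was 0.221, 0.226 and 0.0596 without leaf control 3, leaf Cd 1 and leaf Cd 2.

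Expansins were lower in leaf: EXP2 and exp11 fell among 12 genes, 10 did not pass, among them EXP5 (-1.65, adjusted p = 0.270) and EXPA4 (-1.03, adjusted p = 0.170). The median was -0.98 (camera adjusted p = 0.00235; adjusted p = 0.624 with an estimated correlation). In the completed list of heat shock proteins HSP17.4, MTSHP and ER-SHSP rose and Hsp90-1 (10.16 ± 0.37 to 9.25 ± 0.23, adjusted p = 0.0393) fell among 8 genes (camera adjusted p = 0.0284; adjusted p = 0.624 with an estimated correlation). Of 11 carotenoid synthesis genes PSY2 and LCY1 fell and 9 did not pass (CRTL-E-1, -1.02, had an adjusted p = 0.0387 with arrays paired), with a median of -0.56 (camera adjusted p = 0.0284; adjusted p = 0.624 with an estimated correlation). Both of these lists lost their call without leaf control 1, leaf Cd 2 or leaf Cd 3, with an adjusted p up to 0.141 for heat shock proteins and 0.151 for carotenoid synthesis.

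The other fixed lists tested in leaf were not called, with camera adjusted p between 0.3 and 0.932. Of 25 ethylene genes ERF2 rose, ETR5 (-0.70, adjusted p = 0.0458, and 0.0790 with arrays paired) and PTI4 fell, and EREB (-2.19, adjusted p = 0.0955) and ETR4 (-1.12, adjusted p = 0.0864) did not pass; the median was 0.07 and the mean -0.11 (0 and -0.12 with genes at background at their bound). The ACC oxidase ACO5, which rose in leaf, is not a member of the fixed ethylene list. Of 5 fixed heat shock genes HSP17.4 rose and Hsp90-1 fell, while HSP17-6 (0.32) and HSC80 (0.15) did not pass. Of 5 iron acquisition genes NRAMP3 rose, and Nramp2 (-0.59) did not pass. FER was at background in controls and on 2 of 3 Cd arrays, and NRAMP1 on all leaf arrays. With both at 0 the median was 0 and the mean 0.12. Of 7 jasmonate genes LOX1.1 (-1.37; adjusted p = 0.103, and 0.0413 with arrays paired), loxC (0.77), AOS (0.49) and loxD (0.21) did not pass. Neither did MT2 (0.50), GSH1 (-0.39), MT4 (0.30) and GSH2 (-0.19) of 7 metal chelation genes, P4 (0.56), CHI14 (0.55), CHI9 (0.36) and PR1b1 (0.24) of 9 pathogenesis-related genes, nor LOC543855 (0.79), WRKYIId-4 (0.75), WRKYIId (0.27) and WRKYIId-1 (0.15) of 6 WRKY factors.

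In the small fixed lists 0 genes passed in leaf. The differences were -1.45, -0.57 and -0.19 for CAB5, CAB4 and CAB6A, 0.71 for CEVI-1, 0.73 for PT1, -0.32 for AMT1-2, and -1.86, 1.0 and 0.60 for DFR, CHS2 and CHS1. They were -2.33 and -1.12 for the proteinase inhibitors LOC543954 and ARPI, 0.41, -0.16 and -0.07 for TAS14, NCED1 and ER5, -0.04 for ST2, -0.49 for the trichome marker SSTLE1, 1.17 for pip1, and 0.07 and -0.06 for PP2Ac2 and PP2AC1. MTS1, PT2, ST1 and ext1 were at background in leaves.

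The third comparison asked whether root and leaf responded differently, by the difference between the root and leaf responses. ACO5 rose from background in leaf, by at least 50.2-fold, and did not pass in root (0.21). With background as its leaf control level the difference is a bound, -5.44 or lower (adjusted p = 0.00124 for the fitted difference). The ACC oxidase ACO6 fell in root (-1.59) and did not pass in leaf (0.05), a difference of -1.64 (adjusted p = 0.0133). SODCP.2 fell further in leaf (difference 2.86, adjusted p = 0.00159), and EXP2 fell in leaf and differed by 0.79 in root, where it did not pass (difference 4.19, adjusted p = 0.0133). LOC544276 (3.97), LOC543602 (3.24) and LOC543717 (1.67) rose in root and did not pass in leaf. LOC544282 (-4.69; -3.99 without root Cd 3 and -3.90 with array weights) and LOC544070 (-2.41) rose in leaf and did not pass in root, and sbt3 (1.66) fell in leaf and did not pass in root. Pairing by number was applied to both tissues, although the numbers do not pair the root arrays. With it 4 differences did not pass: LOC544282 (adjusted p = 0.0743), LOC544070 (0.0533), LOC543717 (0.0682) and sbt3 (0.0915). Over all settings their adjusted p reached 0.0879, 0.0540, 0.0683 and 0.109. LOC543602 passed when paired but lost its call in 9 fits with 1 array left out (adjusted p up to 0.0886).

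In all 76 probe sets passed for the difference, 23 with a root minus leaf difference above 0 and 53 below, and 1532 passed at an unadjusted p under 0.05. With arrays paired by number 46 were above 0 and 41 below, and 42 of these 87 were shared with the unpaired count. Without leaf Cd 3, 88 were above 0 and 72 below. The 10 genes named are all the named genes that passed. The root minus leaf difference of the pathogenesis-related list was above 0 (median 1.1, camera adjusted p = 0.000758; adjusted p = 0.376 with an estimated correlation), with medians of 1.06 in root and 0.19 in leaf. So was that of histones and cell cycle, with medians of 0.38 in root and -0.59 in leaf, neither called unpaired (median difference 1.08, or 0.72 with CycB2 at its bound; camera adjusted p = 0.0330; adjusted p = 0.376 with an estimated correlation; up to 0.167 with 1 array left out, without leaf control 3). The count was between 26 (without leaf control 3) and 160 (without leaf Cd 3) with 1 array left out, and ACO5, ACO6, EXP2, LOC544276 and SODCP.2 (5 of 10) kept their call under all settings.

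A further comparison asked how far the called probe sets coincided. SODCP.2, CO1, CIP1, 3OH-2, HY5, PSY2 and LCY1 fell in both tissues, and MTSHP and PMEU1 rose in both. Of all probe sets 27 fell in both (3.04 expected if calls were independent, odds ratio 12, Fisher's exact p = 1.76e-18) and 11 rose in both (2.39 expected, odds ratio 5.23, exact p = 2.53e-05). None rose in root and fell in leaf, and 6 fell in root and rose in leaf (4.4 expected, exact p = 0.457). Probe sets are not independent replicates, and both contrasts share the variance estimate of each probe set. The expected numbers and the Fisher p-values therefore do not give the level of chance. Across all probe sets the differences in root and leaf correlated at r = 0.19 (Spearman's rho 0.13). With the replicate block 60 probe sets changed the same way in both tissues, against 38, and with 1 array left out the number was 17 (root control 1), 22 (root control 3), 16 (root Cd 1), 19 (root Cd 2), 24 (leaf control 2) and 68 (leaf Cd 3) where it moved most.

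**Figure D4:**
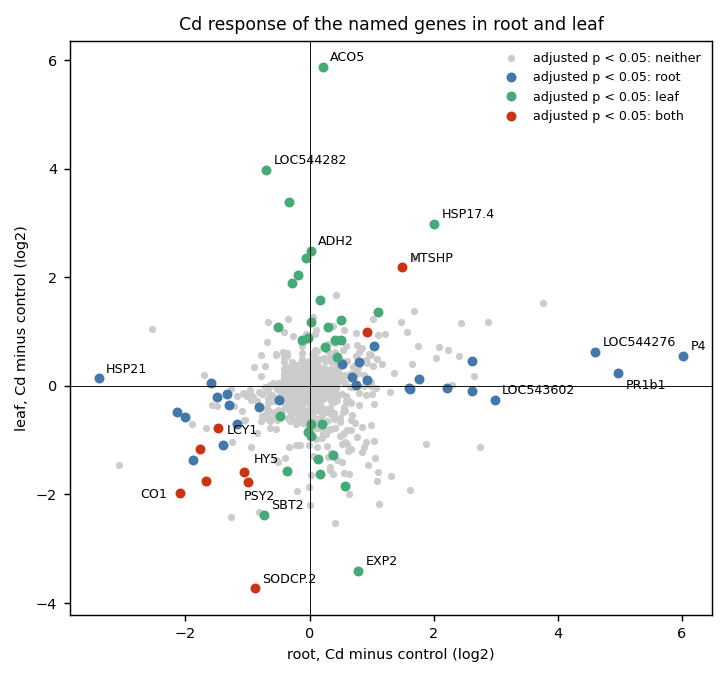
Cd minus control on the log2 scale in root (x axis) and leaf (y axis), with 1 point for each of the 801 named genes, coloured by the tissue in which it passed the adjusted threshold. The 9 genes called in both lie in the lower left (7) or upper right (2), ACO5 lies near 0 in root and at a fitted 5.88 in leaf, where its controls are at background, and P4 at 6.02 in root and 0.56 in leaf.

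The last comparison set untreated roots against untreated leaves, as a description of the tissues. ACO5 was at 11.76 ± 0.49 in roots and at background in leaves, at least 312-fold higher in root. The sulfate transporter ST1 (at least 171-fold), Mdip1 (at least 129-fold) and FER (at least 105-fold) were also at background in leaves. TIP, a tonoplast aquaporin, was at 11.77 ± 0.05 in roots and 4.34 ± 0.94 in leaves (112-fold). In the other direction LOC543989, CEVI-1, the subtilisin-like protease sbt4a, LOC543656 and LOC544001 were at background in roots. As deposited, their bounds were at least 111, 91.6, 69.5, 57.8 and 38.9-fold. With the median difference taken off they were 172, 142, 108, 89.6 and 60.3-fold, and these larger values hold only if that correction does. Also with it taken off, the bound of LOC544001 was 22.4-fold without leaf control 1 and 170-fold without leaf control 3. In the folds of genes higher in root the median difference of 0.63 between root and leaf arrays was taken off, which lowers them. With that difference left in, 7118 probe sets passed, 6119 of them higher in root, and after each array was centred on its median 4343 passed, 50.7% of them higher in root.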

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

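The tests of leaf or root tissue in the other tissue's samples, of the weight of 1 array, and the comparison of the ribosomal RNA control were chosen only after the results were seen.

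The response to Cd differed between root and leaf in 76 probe sets, by a test of the difference itself. The named genes among them had a root minus leaf difference of -4.69 (LOC544282), 4.19 (EXP2), 3.97 (LOC544276), 3.24 (LOC543602), 2.86 (SODCP.2), -2.41 (LOC544070), 1.67 (LOC543717), 1.66 (sbt3) and -1.64 (ACO6). With arrays paired by number in both tissues, although the numbers do not pair the root arrays, LOC544282, LOC544070, LOC543717 and sbt3 did not pass. LOC543602 lost its call in 9 fits with 1 array left out. ACO5 was at background in the leaf controls, so its fitted -5.67 stands only for a bound, -5.44 or lower. Of 100 splits drawn from the 200 joint splits of the root and leaf arrays, 2 gave as many, the real one included. The 80 splits that mixed control and Cd arrays in both tissues gave 0, since mixing puts any Cd difference into the residual, and the 19 others that kept the groups of a tissue gave 1 to 96. The count of splits therefore does not decide whether chance gives 76. The highest other gave 96 and parted all 3 leaf pairs; that split kept the 3 leaf arrays titled as Cd-treated together and moved root Cd 2 among the root controls. For the 38 probe sets that changed the same way in both tissues 1 of 100 did, with 0 as the highest other. Since other splits of a tissue's arrays call at most 5 probe sets, such a count is bound to be near 0 in them, and it does not test whether the calls coincide.

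With camera and the preset correlation, gene lists differed between the tissues' responses too. Among fixed lists the adjusted p was 0.0330 for histones and cell cycle and 0.000758 for pathogenesis-related proteins. Among completed lists it was 0.0175 for cell cycle and histone H1, 0.00173 for expansins, 0.0134 for heat shock proteins, 0.00246 for pathogenesis-related proteins, 0.0175 for pectin, glucan and mannan hydrolases, 0.00318 for photosystem genes and 0.00246 for sulfate, sulfur amino acids and glutathione. With an estimated correlation 0 lists passed, and with fry 0 fixed and 3 completed lists passed. Splits of the arrays were not run for these list differences.

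The 10 splits of 6 arrays are too few for a share under 0.05. The real split gave 304 probe sets in root (highest other 0), 379 in leaf (highest other 5, and 1 among the 3 other splits that part as many pairs) and 7118 between the tissues (highest other 0), each reached by 1 of 10 splits. The real split called 2 fixed lists in root (1 of 10 splits, highest other 1) and 1 in leaf (8 of 10 splits, highest other 3). The count of lists in leaf is thus no more than other groupings of these arrays gave.

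Outside the tested probe sets, the control probe set of the 25S ribosomal RNA was 0.86 higher in the leaf arrays titled as Cd-treated (7.45 ± 0.14 in controls and 8.31 ± 0.26).

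The completed lists of photosystem and carotenoid synthesis genes were called lower in Cd roots, with 1 of 9 and 3 of 11 genes past the threshold. Both calls were lost with an estimated correlation (adjusted p = 0.244 and adjusted p = 0.21 with an estimated correlation). Leaf tissue in the control roots would need a median share of 25.9% for the photosystem genes and would put 5 probe sets restricted to leaf at a median of 8.40. They lay at 2.63, a median of -5.63 from the predicted level. For the carotenoid genes, at a median share of 26.2%, the same distance was -5.65. Both values argue against leaf tissue at the median share. The share needed by the carotenoid genes ran from -130% to 266%, so no single share would account for all of them. A single array does not account for the photosystem fall either, since the list's median stayed at -0.64 or lower whichever root array was left out (-0.64 without root control 3, -0.95 with all). Green tissue other than leaf, light on the roots, the hour of harvest and Cd itself stay open and were not tested.

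Of 224 probe sets higher in the leaf arrays titled as Cd-treated, 25 were also higher in control roots than in control leaves. The cut was a difference at least 2 above the median root minus leaf difference on the log2 scale. Among the 25 were ADH2, LOC543598, LOC544070, 20ox-2, ctu1 and LePCL1 (adjusted p = 0.0520 with arrays paired) beside ACO5. LOC543598 did not pass with arrays paired either (adjusted p = 0.0839). The same leaf controls enter both the root minus leaf difference and the rise in leaf, so a low control value favours both. Whether 25 is more than that alone gives was not tested. Root tissue in those leaf samples would need a median share of 14.8% (2.87% to 89.8% over the 25). It would put ST1 at 8.16, Mdip1 at 7.76 and FER at 7.47, where 2.52, 2.31 and 2.79 were measured. Over 11 probe sets restricted to root the median distance was -5.42, which argues against root tissue. A response of the leaves stays open as a hypothesis, limited by the source label that calls the same leaves untreated.

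The completed list of pathogenesis-related proteins was called higher in Cd roots, with 3 of 14 genes past the threshold (adjusted p = 0.21 with an estimated correlation). Some members are abundant in leaf, such as PR1b1 (11.19 ± 0.49 in leaf controls). Leaf tissue in the Cd roots would need a median share of 48.2% and would put LOC543989 at 9.07, where 2.47 was measured. The share needed ran from 0.144% to 1251% over the members, so no single share would account for all of them. Over 6 probe sets restricted to leaf the median distance was -6.25, which argues against leaf tissue at the median share. The list's median was 1.37 with all arrays (1.05 with genes at background at their bound) and 0.82 without root Cd 2, the nearest to 0 of the 6 values with 1 root array left out, so a single array does not account for the rise, although it accounts for part of its size. Cd itself stays open and was not tested apart from other differences between the root groups.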

How the results depend on the processing

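The completed gene lists were added after the annotation was seen, and the replicate block with an estimated correlation after the results were seen; the other settings were planned. Named genes gave 3555 values under the alternatives. Of these 3255 kept direction and call, 184 lost the call and 71 gained it. Another 45, which passed neither with nor without the alternative, changed sign, and 0 called values reversed. For a root or leaf contrast the trended prior, probe set filters, 2-fold minimum, replicate block and leaving out the other tissue's arrays cannot change the log2 difference. Kept directions and absent reversals are thus partly fixed in advance. Genes not called gave 967 of the kept values in root and 1098 in leaf. Of called values 74 lost the call and 417 kept it in root, 73 and 422 in leaf, 37 and 160 for the difference. The cause of the changes was not tested, except that probe sets above the median brightness and fits on fewer arrays test fewer probe sets or samples, and a 2-fold minimum keeps part of the same calls. The main fit shares 1 spread per probe set over the 4 groups. Between leaf arrays titled as Cd-treated the SD of the difference was 0.57 to 0.72. It was 0.43 to 0.50 in leaf control, 0.28 to 0.52 in root control and 0.38 to 0.52 in root Cd. The shared spread can thus be too small for the leaf contrast, and its p-values too low.

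Above the median brightness 175 root, 239 leaf, 37 difference and 3728 root-against-leaf probe sets passed. Array weights gave 3745 in root and 705 for the difference. The 6 arrays of a tissue alone gave 202 in root and 65 in leaf, and quantile normalization within leaf gave 72. A 2-fold minimum gave 207 in leaf and 3308 for root against leaf, where median centring gave 4343 and quantile normalization over all arrays 4251. The replicate block gave 421 in root, 376 in leaf, 87 for the difference, 7031 for root against leaf and 60 for the overlap.

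With 1 array left out the counts were 85 to 409 in root, 127 to 589 in leaf, 26 to 160 for the difference, 6166 to 7530 for root against leaf and 16 to 68 for the overlap. For the difference, the count was 40, 43 and 37 without root control 1, 2 and 3, 39 without root Cd 1, 28 and 26 without leaf control 2 and 3, 50 without leaf Cd 2 and 160 without leaf Cd 3.

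Of the fixed lists, 0 were called in root and 0 in leaf with an estimated correlation, 0 in leaf with fry, 4 in root and 2 in leaf with the replicate block, 0 and 0 with that block and an estimated correlation, and 7 and 4 with the lists completed by symbol. With 1 array left out 1 to 3 lists were called in root (1 without root control 1) and 0 to 3 in leaf (0 without leaf control 3 or leaf Cd 2, 3 without leaf Cd 3). Signal near background limits the genes given as bounds.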

Other observations

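The test of copper supply was chosen only after the result was seen, and the genes of this part were chosen after their values were seen.

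In the hormone lists completed by symbol few genes passed. Of 11 ethylene synthesis genes ACO6 fell in root and ACO5 rose in leaf, and 9 passed in neither tissue (camera adjusted p = 0.138 in root and 0.626 in leaf). Of 8 gibberellin genes the 3-oxidase 3OH-2 fell in both tissues, while the 20-oxidase 20ox-2 rose in leaf (list adjusted p = 0.0619 in root and 0.166 in leaf). Among 15 ERF and DREB factors ERF2 and DREB3 rose and PTI4 fell in leaf, and 0 passed in root (list adjusted p = 0.334 in root and 0.967 in leaf; the leaf median was -0.05 and the mean 0.07). Of 9 genes of ABA and dehydration NCED1 fell in root and 0 passed in leaf (list adjusted p = 0.481 in root and 0.433 in leaf; the root median was -0.29 and the mean 0.05).

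Cell wall hydrolases of pectin, glucan and mannan included PMEU1 and TBG1, which rose in root, and PMEU1, which rose, and TBG6, which fell, in leaf, among 25 genes (list adjusted p = 0.102 in root and 0.267 in leaf). Of 10 xyloglucan endotransglucosylases, 9 wound-response defence proteins, 7 phosphate starvation genes and 5 ribosomal proteins, 0 passed in root and 0 in leaf, with list adjusted p between 0.258 and 0.971. With arrays paired by number in both tissues, XTH7 (-2.52, adjusted p = 0.0193) and the phosphate starvation gene TPSI1 (-1.13, adjusted p = 0.0433) passed in leaf. So did the hydrolases TBG1 (0.74, adjusted p = 0.0442) and TBG7 (-1.39, adjusted p = 0.0444).

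Of 4 transcripts of copper enzymes and chaperones, picked after their values were seen and not tested as a list, SODCP.2 (-3.73) and its chaperone CCS (-0.84) fell in the leaf arrays titled as Cd-treated. CCH (0.72) rose, and SODCC.1 (-0.63, adjusted p = 0.0561) did not pass. As a hypothesis, a lower copper supply in those leaves may account for the fall of SODCP.2 and CCS, and it predicts a rise of the iron superoxide dismutase FESOD. The brighter FESOD probe set differed by -0.58 (95% interval -1.21 to 0.036) and the other by 1.54 (adjusted p = 0.0537). They differ in sign and neither passed, so the hypothesis stays undecided.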
